A study of Mus musculus with 4 samples.

How the data were processed

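The series held 4 arrays of the mouse cell line NSCL61, 2 labelled as the line alone and taken here as controls and 2 labelled as carrying the shRNA, which the series title assigns to Eva1. Per the labels, total RNA was prepared with a column kit, amplified and labelled with Cy5, and hybridised in 1 colour to a 3D-Gene mouse chip. Per the labels' protocols, transfected cells were selected with hygromycin before RNA was taken. The labels do not say whether the control cells were selected in the same way beyond the series title, which speaks of a control hairpin.

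The deposited intensity values were on a linear scale and were scaled by the authors so that the median of the filled cells was near 25 on each array, as the values themselves show. The scanner, the background correction and the rule by which cells were left blank are not given in the sources used here. Blank cells made up 12.0% and 10.8% of probes on the control arrays and 6.95% and 8.35% on the Eva1 shRNA arrays. Probes with a value on all 4 arrays numbered 19199, 500 were blank on all 4 and 3774 were blank on 1 to 3. Of the last, 433 were blank on both control arrays alone and 101 on both Eva1 shRNA arrays alone, and none of these averaged above the array median of 25, the highest mean being 19.97. No fold was computed for a blank cell in the main setting, while an alternative filled blank cells with the lowest value of the array. The number of arrays limits the precision, with 2 residual degrees of freedom per gene.

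Of 23473 probes, 16631 had 1 gene symbol in the platform annotation, 0 had several and 6842 had none. Symbols were updated through a RefSeq gene table of the mouse assembly GRCm38.p6, used only for names: 12622 were current, 3947 were updated from an older synonym, 59 were ambiguous and kept, and 3 were unmatched and kept. The names Krt20, Plet1, Tmem171 and Tmem176b, for example, replaced older clone or predicted names. No coordinates are given, since no genome build is named for the probes. List members and family members of Mpzl2 without a named probe were not analysed here.

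Log2 intensities of the 19199 probes measured on all 4 arrays were used. The array medians over these probes differed by 0.274 on the log2 scale, above the limit of 0.1 set for using the values as deposited, so the arrays were quantile normalized (limma 3.58.1 in R 4.3.3). Each gene was represented by the probe with the highest mean log2 value, which left 13765 genes. Groups were compared with limma's lmFit and eBayes without trend, two-sided, with Benjamini-Hochberg adjustment over genes, or over probes for Mpzl2, and a threshold of 0.05. Replicates correlated at r = 0.991 (control) and 0.993 (Eva1 shRNA) across probes, and arrays of different groups at 0.964 to 0.970. Probes are not independent replicates.

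The groups, the test, the alternatives, the 21 gene lists and the rule for named genes were fixed before the data were examined. The rule took Mpzl2 and its family, the 12 largest rises and the 12 largest falls among genes that passed the test, did not overlap between groups and had the higher group's mean above the median of genes, and up to 4 members of each list with the smallest p. Predicted genes and clone names were passed over. The rule gave 107 genes, of which 99 passed the test, and 39 more were named after their values were seen. The 20 lists other than housekeeping genes were tested with limma camera at a preset correlation of 0.01, with the correlation estimated, and with fry, with Benjamini-Hochberg adjustment over the lists. With the correlation estimated, camera's test rests on the 2 residual degrees of freedom, which leaves it little power here. The gene Bcl2l1 was in 2 lists.

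The alternatives were the authors' scaling, median centring, leaving out the dimmest 25% of probes, adding 16 intensity units before log2, filling blank cells with the lowest value of the array, the replicate number as a block, eBayes with trend or robust, the mean of a gene's probes, a threshold of 0.1, limma treat against a 1.5-fold change, camera on ranks, and each array left out in turn. Counting every probe, named or not, was added after the data were seen.

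The analysis was tested on simulated data for the comparison of Eva1 shRNA with control, with 13765 genes of which 200 were changed. At a 1.5-fold change 0 of 67 genes were recovered, at 2-fold 4 of 67 (5.97%) and at 4-fold 56 of 66 (84.8%). In the data 3576 genes were called, and the adjustment is stricter where few genes change. These recovery rates therefore do not carry over to the data. There were 4 false calls, 6.25% of the calls. Camera gave p under 0.05 for 1 of 100 lists without a shift. The simulated noise was independent between genes, while the estimated correlation in the data reached 0.497 for the interferon response list. That count therefore does not measure false list calls in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.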

Results

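The data were messenger RNA levels in NSCL61, a mouse glioma-initiating cell line made from neural stem cells by overexpressing an oncogenic HRas on a p53-deficient background. Cells that carried a short hairpin RNA (shRNA) against Eva1 were compared with control cells, with 2 arrays in each group. Eva1 is named Mpzl2 in current mouse nomenclature and encodes a cell adhesion protein of the immunoglobulin superfamily. Each array was a 1-colour 3D-Gene mouse chip with 23473 probes. The arrays gave values for 20662 and 20934 probes in the control cells and for 21842 and 21513 probes in the Eva1 shRNA cells. Levels are given as log2 of the scaled intensity after quantile normalization, and log2 changes are Eva1 shRNA minus control. Nothing in the descriptions says that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

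The targeted gene was lower on both Eva1 shRNA arrays. Mpzl2 had deposited intensities of 55.0 and 54.4 on the control arrays and of 8.20 and 6.21 on the Eva1 shRNA arrays, with means of 54.7 ± 0.376 and 7.21 ± 1.41 (SD, n = 2 each). After normalization Mpzl2 was 8.72-fold lower, a log2 change of -3.12 with a standard error of 0.17 (limma, two-sided, adjusted p = 0.00172 over 19199 probes). With 16 intensity units added before log2, which damps changes of dim probes, the log2 change of Mpzl2 was -1.71. Without them it was the fall of rank 25 among all 13765 genes tested. Its Eva1 shRNA intensities lay in the range of probes that were blank on some arrays, so that rank is not settled. Mpzl1, a related family member, had a log2 change of -0.66 and passed the test over genes (adjusted p = 0.0404) but not over probes (adjusted p = 0.0507). The call of Mpzl1 was lost under the authors' scaling, with blank cells filled and whichever array was left out, with the highest adjusted p (0.179) without Eva1 shRNA array 2.

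The comparison asked which genes differ when Eva1 is knocked down, in a series whose stated interest is the proliferation of glioma-initiating cells. Acta2, Ddit4l, Mgp and Bgn were among the largest rises, and Aqp8, Krt20, Calca and Pdk1 were among the largest falls. Acta2, the smooth muscle alpha-actin gene, rose from a log2 level of 2.18 ± 0.01 to 8.40 ± 0.21 (SD, n = 2 each). Its control intensities of 4.04 and 4.38 lay in the range of probes that were blank on some arrays, so the size of its change is not settled, and with 16 intensity units added the log2 change was 4.10 in place of 6.22. Krt20, a keratin gene bright in the control cells, was 19.9-fold lower, and Aqp8, a water channel gene, had a log2 change of -4.70, or -3.29 with 16 units added. Of the 13765 genes tested, 1720 were higher and 1856 were lower in the Eva1 shRNA cells at adjusted p under 0.05 (limma, two-sided). Of these, 712 were at least 2-fold higher and 882 at least 2-fold lower, and with 16 units added 379 and 492 genes were called at that distance. Counted at any distance, more genes were called with 16 units added, 2444 higher and 2469 lower.

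The 12 named rises were led by Acta2, with a log2 change of 6.22. Ddit4l, a relative of the mTOR inhibitor Ddit4, rose by 4.83 and Tmem171 by 4.54. Qrfpr, a neuropeptide receptor gene, had a log2 change of 5.37, but its control intensities of 2.31 and 1.49 stood near the lowest of those arrays (1.44 and 1.42), and with 16 units added the change was 2.39. The extracellular matrix genes Mgp (matrix Gla protein) and Bgn (the proteoglycan biglycan) rose by 4.24 and 4.05. Mgp had the largest standard error of the 12, at 0.51, because its level differed between the Eva1 shRNA arrays (SD 1.14). Trim47 rose by 4.23, Pir by 4.02, the transporter gene Slco3a1 by 3.94, the potassium channel subunit gene Kcnmb4 by 3.87, the small heat shock protein gene Hspb8 by 3.85 and Tmem176b by 3.76. The standard errors of the other 11 lay between 0.15 and 0.30. After adding 16 units the changes of Acta2 (4.10), Slco3a1 (2.18) and Kcnmb4 (2.16) were also smaller by over 1.5 times.

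The 12 named falls began with Aqp8 at a log2 change of -4.70, Krt20 at -4.31, Calca at -4.11 and Plet1 at -3.90. Calca encodes calcitonin and a neuropeptide made from the same gene. The related gene Calcb, named after its value was seen, had a log2 change of -3.20, and signal shared between probes of these related genes was not excluded. On the scale with 16 units added, the change of Calca was -2.46. Ero1a, an oxidase of the endoplasmic reticulum, had a log2 change of -3.72, Ankrd37 -3.53, Stc1 (stanniocalcin) -3.53 and Pdk1 (pyruvate dehydrogenase kinase) -3.50. The remaining falls were Asgr1 at -3.73, Chrna1, an acetylcholine receptor subunit gene, at -3.71, Cd93 at -3.53 and Cbln1 at -3.52. For 13 of the 24 genes the dimmer group's mean intensity was under the array median of 25, where the size of a change depends on the signal near background. Adjusted p-values of all 24 genes in limma's test lay between 8.739e-04 and 0.00515. The genes were chosen from these same arrays for passing that test with large changes, so the small values are no added support.

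**Figure D1:**
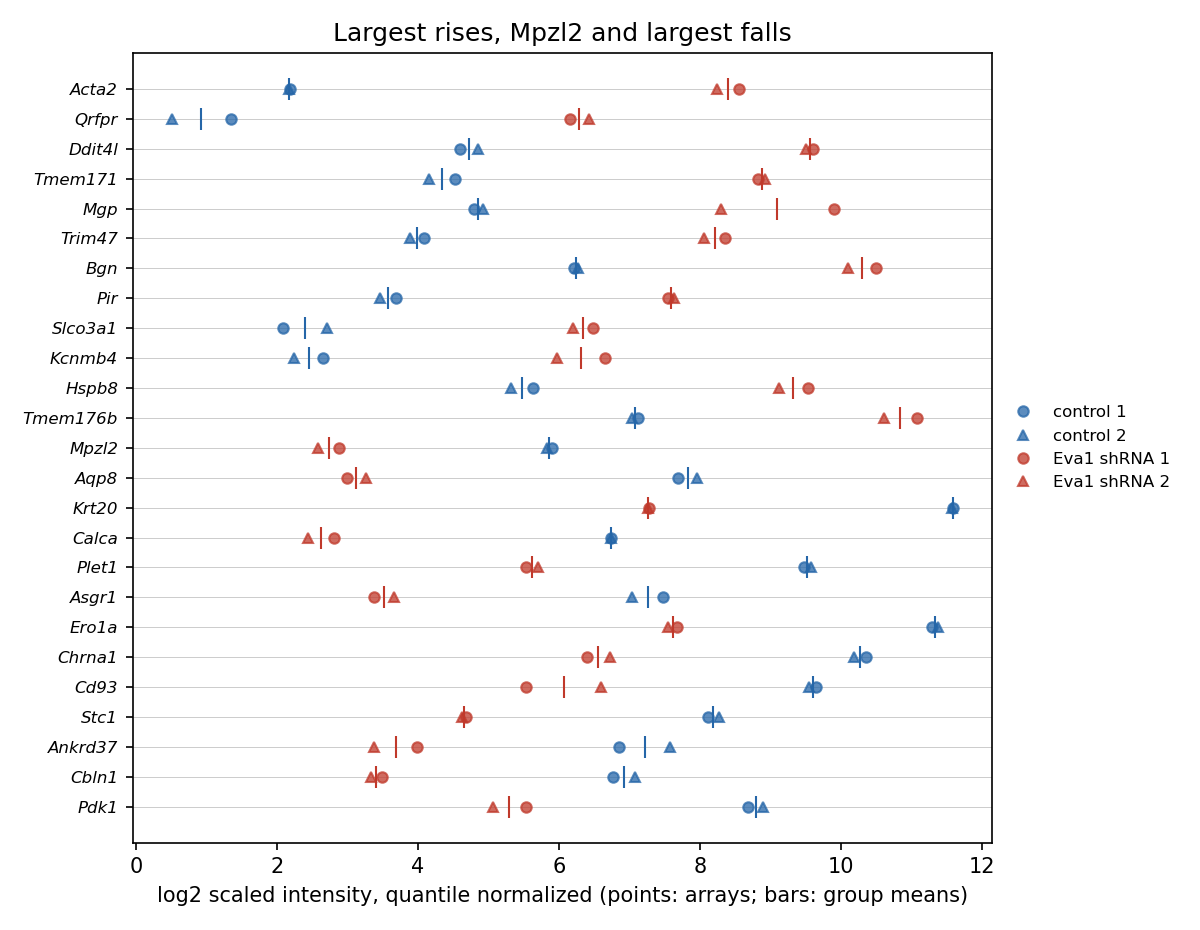
Log2 scaled intensity (x axis) of the 12 named rises, Mpzl2 and the 12 named falls, with circles and triangles for arrays 1 and 2 of each group and bars for group means. Acta2 moved from a mean of 2.18 to 8.40 and Krt20 from 11.58 to 7.27.

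By size alone, 1659 genes had group means at least 2-fold apart with no overlap between the groups, 745 higher and 914 lower, but with 16 intensity units added, which damps the changes of dim probes, only 873 did, 380 higher and 493 lower. Groups of any distance did not overlap for 66.7% of genes, against 33.3% by chance. The balance of higher and lower calls depended on the scaling between arrays. After quantile normalization 48.1% of the calls were higher, and the median change over all genes was -0.01. With the authors' scaling alone the calls were 2714 higher and 1295 lower, 67.7% higher, and the median change was 0.18. Against median centring, the authors' scaling raised the log2 change of every gene by 0.209, so a list median near 0 can turn positive under it with no change relative to other genes. With 1 array left out, the total of 3576 calls became 1828 (without control array 1), 2300 (without control array 2), 1279 (without Eva1 shRNA array 1) and 1462 (without Eva1 shRNA array 2).

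**Figure D2:**
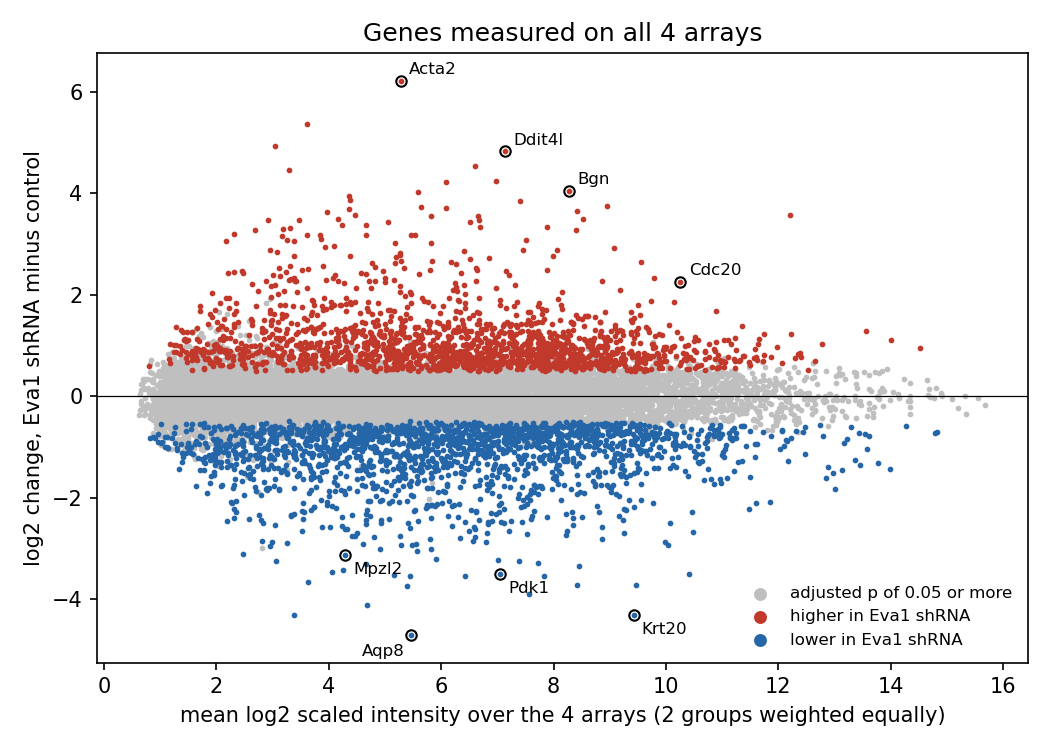
Log2 change (y axis, Eva1 shRNA minus control) against mean log2 scaled intensity (x axis) for the 13765 genes tested, with the 1720 higher genes in red, the 1856 lower genes in blue and the others in grey. Among the labelled genes are Acta2 (6.22) and Aqp8 (-4.70), the largest rise and fall under the naming rule, and Mpzl2 (-3.12).

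Most tested genes of the cell division list were higher in the Eva1 shRNA cells. Of 30 tested members of the cell cycle and proliferation list, 21 rose, 0 fell and 9 did not pass the test, and 25 rose when adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, rose by 2.26, the cyclin gene Ccna2 by 1.88, the mitotic kinase gene Plk1 by 1.78 and the replication helicase gene Mcm5 by 1.46. The median change of the list was 0.83. The list stood above other genes at camera's preset correlation (limma camera, two-sided, adjusted p = 6.368e-10), and the adjusted p = 0.418 with an estimated correlation. Fewer members passed with 1 array left out: 15 and 18 without control arrays 1 and 2, and 11 and 10 without Eva1 shRNA arrays 1 and 2.

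Most members of a combined list of genes induced by low oxygen and genes of glycolysis were lower in the Eva1 shRNA cells. Of 18 tested members of the hypoxia and glycolysis list, 12 fell, 1 rose and 5 did not pass, and adjusted over the list alone 14 fell and 1 rose. Ankrd37 had a log2 change of -3.53, Pdk1, which restrains pyruvate oxidation, -3.50, the oxygen-sensing hydroxylase gene Egln3 -2.65 and the glucose transporter gene Slc2a1 -1.56. The collagen hydroxylase gene P4ha1 (-2.05) and the angiogenic factor gene Vegfa (-1.06) also fell, and the glycolytic regulator gene Pfkfb3 (0.64) was the member that rose; these 3 were named after their values were seen. With 16 units added the change of P4ha1 was -1.32. The median change was -0.95 (camera adjusted p = 8.704e-06, and adjusted p = 0.672 with an estimated correlation). The members that fell numbered 8, 10, 7 and 7 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2, and 0 rose in each case. The adjusted p of Vegfa reached 0.0758 without control array 1 and that of Pfkfb3 0.142 without Eva1 shRNA array 1.

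Several genes of cholesterol synthesis were higher. Of 13 tested members of that list, 4 rose, 1 fell and 8 did not pass, and adjusted over the list alone 9 rose and 1 fell. The sterol enzyme genes Nsdhl (1.22), Cyp51 (0.99) and Idi1 (0.79) rose, as did Insig1 (0.64), a regulator of the pathway named after its value was seen, and Dhcr7 had a log2 change of -0.57. The median change was 0.48 (camera adjusted p = 0.0402, and adjusted p = 0.672 with an estimated correlation). The members that rose numbered 2, 2, 2 and 1 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2, and 0 fell in each case. The list's adjusted p was 0.0686 with the authors' scaling, 0.0729 with median centring, 0.0631 without the dimmest 25% of probes, 0.106 without control array 2 and 0.0606 without Eva1 shRNA array 2, and it ran from 0.0121 to 0.672 over all alternatives. Nsdhl kept its call whichever array was left out, and the adjusted p reached 0.059 for Cyp51, 0.136 for Idi1 and 0.174 for Insig1 without Eva1 shRNA array 2 and 0.182 for Dhcr7 without Eva1 shRNA array 1. The call of Dhcr7 was also lost with the authors' scaling.

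These 3 lists were the ones called among 20 tested with camera, which asks whether a list's genes shifted more than other genes. With the correlation estimated for each list, 0 lists were called, in a test that rests on 2 residual degrees of freedom. The estimated correlation was 0.0079 for the cell cycle list, below the preset 0.01. Correlation between its genes therefore does not account for the loss of its call. For the hypoxia and cholesterol synthesis lists the estimates were 0.077 and 0.023. Fry, which asks only whether a list's genes moved, on balance, one way and does not compare them with other genes, called 10 lists, among them cell cycle (adjusted p = 0.00748), hypoxia (0.0221) and cholesterol synthesis (0.0264). Over all 13765 genes tested 1720 rose and 1856 fell, and the counts of a list are to be read beside that share. In the paragraphs that follow, members beyond the 4 of the naming rule were named after their values were seen. For a gene whose call was lost when an array was left out, the highest of the 4 adjusted p-values is given with the array whose omission gave it. Of the 137 named genes that passed the test, 31 had a log2 change over 1.5 times smaller with 16 intensity units added, and that value is given for them.

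**Figure D3:**
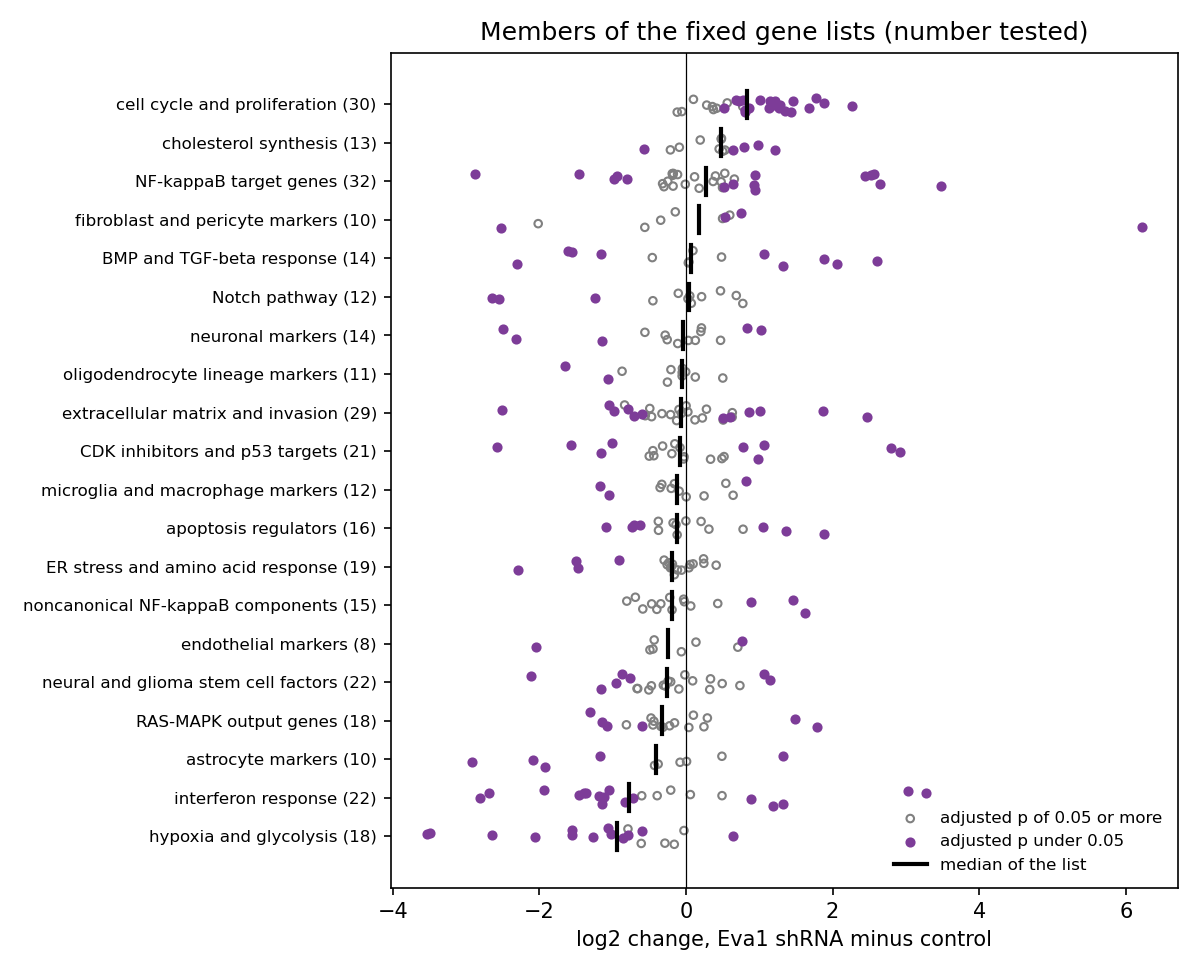
Log2 change (x axis, Eva1 shRNA minus control) of each tested member of the 20 gene lists, with filled points for genes at adjusted p under 0.05, open points for the others and a bar at each list's median. The median was 0.83 for the cell cycle list and -0.95 for the hypoxia list, and most other lists had members that moved both ways.

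Interferon response genes changed in both directions. Of 22 tested members, 12 fell, 5 rose and 5 did not pass, with the same counts of 12 and 5 adjusted over the list alone. Bst2 (tetherin) had a log2 change of -2.68 and Oas2, an antiviral oligoadenylate synthetase gene, -1.94. The chemokine gene Cxcl10 rose by 3.27 and the guanylate-binding protein gene Gbp2 by 3.02, and the others that rose were Ifit2 (1.32), Ifit3 (1.19) and Rsad2 (0.89). The median change was -0.78 and the list was not called (camera adjusted p = 0.151), although it was called with the authors' scaling (0.0236) and without Eva1 shRNA array 2 (0.0156). Over all alternatives its adjusted p ran up to 0.852, the value with an estimated correlation. The members that fell numbered 6, 7, 5 and 10 and those that rose 4, 3, 4 and 2 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2. The adjusted p reached 0.0592 for Ifit2 and 0.0846 for Rsad2 without Eva1 shRNA array 2 and 0.133 for Ifit3 without control array 1. After adding 16 units the change was -0.52 for Oas2 and 0.57 for Ifit2.

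NF-κB target genes changed in both directions, and a few components of the noncanonical NF-κB pathway rose. Levels of these components do not measure the activity of the pathway, and the list member Map3k14 had no named probe. Of 32 tested targets, 10 rose, 5 fell and 17 did not pass (11 rose and 5 fell adjusted over the list alone), with a median change of 0.27 (camera adjusted p = 0.223, fry 0.0136). The chemokine gene Ccl20 rose by 3.48, the adhesion gene Vcam1 by 2.64 and the signalling adaptor gene Traf1 by 2.53. The 5 that fell were the plasminogen activator gene Plau (-2.88), Ier3 (-1.46), Tnfaip2 (-0.99), Nfkbiz (-0.95) and Lcn2 (-0.81). The targets that rose numbered 5, 7, 5 and 5 and those that fell 4, 3, 3 and 2 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2. Of 15 tested noncanonical components, 3 rose, 0 fell and 12 did not pass, also adjusted over the list alone. These were the ubiquitin ligase gene Birc3 (1.62), the lymphotoxin receptor gene Ltbr (1.45) and Traf2 (0.88), and Tnfrsf4 had -0.59 without passing (adjusted p = 0.0598), although it passed without the dimmest 25% of probes (0.0158), with 16 units added (0.0289) and with eBayes trend (0.0219). Leaving out an array in the same order, 3, 3, 2 and 2 components rose and 0, 1, 0 and 0 fell. The median was -0.19 and camera's direction was down, while the mean was 0.05 (camera adjusted p = 0.963), and the median was 0.0029 with the authors' scaling. When an array was left out, the adjusted p reached 0.0705 for Traf2, 0.0734 for Tnfaip2 and 0.117 for Nfkbiz without Eva1 shRNA array 1 and 0.147 for Lcn2 without Eva1 shRNA array 2, and Nfkbiz and Lcn2 were also lost with the authors' scaling and Lcn2 with blank cells filled. On the scale with 16 units added, the change was 1.46 for Ccl20, 0.91 for Traf1, -1.11 for Plau and 0.55 for Birc3.

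Neural and glioma stem cell factors were mixed. Of 22 tested members, 5 fell, 2 rose and 15 did not pass (7 and 2 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.225, fry 0.00262). The laminin receptor subunit gene Itga6 had a log2 change of -2.12, the radial glia gene Fabp7 -1.15, Klf4 -0.96, Sox9 -0.87 and the hyaluronan receptor gene Cd44 -0.76. The polycomb gene Bmi1 rose by 1.14 and the mitotic kinase gene Melk by 1.07. Among these genes the adjusted p reached 0.068 for Klf4 and 0.12 for Cd44 without Eva1 shRNA array 1, and 0.0627 for Melk, 0.0709 for Bmi1 and 0.0722 for Sox9 without Eva1 shRNA array 2. Cd44 was also lost with the authors' scaling. The members that fell numbered 4, 4, 2 and 2 and those that rose 1, 3, 1 and 0 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2. With 16 units added the change was -0.59 for Fabp7 and -0.28 for Cd44.

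Some glial and neuronal genes were lower. Of 10 tested astrocyte markers, 4 fell, 1 rose and 5 did not pass (4 and 2 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.172, fry 0.0297). Clu (clusterin) had a log2 change of -2.92, Ndrg2 -2.08, Aldoc -1.92 and Sparcl1 -1.18, while the gap junction gene Gja1 rose by 1.32. Of 11 tested oligodendrocyte lineage markers, 2 fell and 9 did not pass, with the same count of 2 adjusted over the list alone: Pdgfra, the growth factor receptor of oligodendrocyte precursors, at -1.66 and the myelin enzyme gene Cnp at -1.06. Their median was -0.05, and 0.16 with the authors' scaling (camera adjusted p = 0.281, fry 0.024). Of 14 tested neuronal markers, 3 fell, 2 rose and 9 did not pass, with the same counts adjusted over the list alone. The neurofilament genes Nefl (-2.49) and Nefm (-2.32) and the growth cone gene Gap43 (-1.14) fell, and Elavl4 (1.02) and Tubb3 (0.84) rose. The neuronal median was -0.04, and 0.17 with the authors' scaling (camera adjusted p = 0.776). The adjusted p rose to 0.0612 for Cnp, 0.0616 for Gap43 and 0.0635 for Elavl4 without Eva1 shRNA array 1 and 0.15 for Tubb3 without Eva1 shRNA array 2, and Tubb3 was also lost with blank cells filled. The neuronal members that rose numbered 1, 2, 1 and 0 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2. After adding 16 units the change was -0.92 for Nefm and 0.42 for Elavl4.

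CDK inhibitors and genes listed as p53 targets went both ways. The line was made on a p53-deficient background, so these changes do not measure p53 activity. Of 21 tested members, 5 rose, 4 fell and 12 did not pass (6 and 4 adjusted over the list alone). The median was -0.08, but the mean was 0.07 and camera's direction was up (adjusted p = 0.963), and the median was 0.0892 with the authors' scaling. The apoptosis genes Pmaip1 (2.92) and Perp (2.79) rose, with the CDK inhibitor gene Cdkn2c (1.06), Eda2r (0.98) and Aen (0.78). The CDK inhibitor genes Cdkn2a (-2.58) and Cdkn1a (-1.16) fell, with Phlda3 (-1.56) and Gadd45a (2.01-fold lower). Without an array, the adjusted p reached 0.0555 for Cdkn2c, 0.0544 for Gadd45a, 0.0703 for Cdkn1a and 0.148 for Aen without Eva1 shRNA array 1 and 0.0778 for Eda2r without Eva1 shRNA array 2. The members that rose numbered 5, 4, 2 and 3 and those that fell 3, 3, 2 and 4 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2. On the scale with 16 units added, the change of Eda2r was 0.14 and its call was lost, as it was with eBayes trend, and Aen was lost with blank cells filled.

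Among 16 tested apoptosis regulators, 3 rose, 4 fell and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.963). The inflammatory caspase gene Casp1 (1.89), the death receptor gene Fas (1.36) and Bid (1.04) rose. Xiap (-1.09), an inhibitor of caspases, Casp9 (-0.73), Bcl2l11 (-0.71) and Apaf1 (-0.62) fell. The median was -0.13, the mean 0.08 and the median with the authors' scaling 0.04. The adjusted p reached 0.0625 for Bid and 0.2 for Apaf1 without Eva1 shRNA array 1 and 0.0668 for Xiap, 0.122 for Casp9 and 0.13 for Bcl2l11 without Eva1 shRNA array 2. Casp9, Bcl2l11 and Apaf1 were also lost with the authors' scaling and Apaf1 with blank cells filled. The members that fell numbered 1, 1, 0 and 0 and those that rose 3, 4, 2 and 3 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2. With 16 units added the change was -0.57 for Xiap, -0.34 for Casp9 and -0.38 for Apaf1.

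Several feedback genes of RAS and MAPK signalling changed, in both directions. Of 18 tested members, 4 fell, 2 rose and 12 did not pass (7 and 2 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.223, fry 0.0727). The pathway inhibitor genes Spry4 (-1.31), Dusp6 (-1.15), Spred2 (-1.07) and Spred1 (-0.59) fell, while Spry1, another inhibitor of the same family, rose by 1.48 and the ephrin receptor gene Epha4 by 1.79. When an array was left out, the adjusted p reached 0.0526 for Epha4 and 0.203 for Spred1 without Eva1 shRNA array 1 and 0.0702 for Spred2 without Eva1 shRNA array 2, and Spred1 was also lost with the authors' scaling and with blank cells filled. The members that fell numbered 3, 3, 3 and 2 and those that rose 2, 2, 1 and 2 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2. After adding 16 units the change was 0.31 for Epha4 and -0.23 for Spred2, whose call was lost.

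The members called in the amino acid and stress response list and in the Notch list were all lower, but camera called neither list. Of all 13765 genes tested 1856 fell and 1720 rose, so counts of this size need not mark a list. In the Notch list 7 members had positive changes. Of 19 tested ER stress and amino acid response genes, 4 fell, 0 rose and 15 did not pass, with the same count of 4 adjusted over the list alone (median -0.18, camera adjusted p = 0.201, fry 0.0189). Chac1, which degrades glutathione, had a log2 change of -2.29, Vldlr -1.50, Trib3 -1.48 and the asparagine synthetase gene Asns -0.92. Of 12 tested Notch pathway genes, 3 fell, 0 rose and 9 did not pass, also adjusted over the list alone. The target gene Hey1 (-2.64) and the ligand genes Jag1 (-2.55) and Dll1 (-1.24) fell, while Maml2 had -0.45 without passing (adjusted p = 0.0617), although it passed without the dimmest 25% of probes (0.0247). The Notch median was 0.04, but the mean was -0.39 and camera's direction was down (adjusted p = 0.469, fry 0.0485). Without the arrays' dimmest probes the Notch median was -0.22, and 1 Notch gene rose without control array 1 and 1 without Eva1 shRNA array 2. The adjusted p of Asns reached 0.0752 without Eva1 shRNA array 2.

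Genes responding to BMP and TGF-β changed in both directions. Of 14 tested members, 5 rose, 4 fell and 5 did not pass, with the same counts adjusted over the list alone (median 0.07, camera adjusted p = 0.768). Among the Id genes, which encode inhibitors of differentiation factors, Id2 (2.61) and Id4 (2.06) rose and Id3 (-1.56) and Id1 (-1.16) fell. Bambi (1.89), a BMP pseudoreceptor, Ccn2 (1.32) and Ccn1 (1.06) rose, and Tgfbi (-2.30) and Smad7 (-1.61) fell. Among these genes the adjusted p reached 0.0669 for Ccn2 and 0.0501 for Id1 without Eva1 shRNA array 2 and 0.0597 for Id3 without control array 1. On the scale with 16 units added, the change of Ccn2 was 0.50.

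Extracellular matrix and invasion genes also moved both ways. Of 29 tested members, 6 rose, 6 fell and 17 did not pass (8 and 9 adjusted over the list alone), with a median of -0.06, and 0.12 with the authors' scaling (camera adjusted p = 0.963). Timp3, an inhibitor of matrix metalloproteinases, rose by 2.47 and the transcription factor gene Snai2 by 1.87. The matrix protein gene Thbs1, for thrombospondin, had a log2 change of -2.51 and the fibronectin receptor subunit gene Itga5 -1.05. The adjusted p of Itga5 reached 0.0584 without Eva1 shRNA array 1. The members that rose numbered 4, 3, 2 and 2 and those that fell 3, 3, 1 and 2 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2. With 16 units added the change was 1.62 for Timp3, 1.07 for Snai2 and -0.62 for Itga5.

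Markers of other cell types moved singly, and camera called none of their lists. Of 10 tested fibroblast and pericyte markers, 3 rose, 1 fell and 6 did not pass (5 and 2 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.432, fry 0.0297) that became -0.17 with blank cells filled. Beside Acta2 (6.22), the collagen gene Col1a2 rose by 0.76 and Pdgfrb by 0.54, while the pericyte gene Rgs5 fell by 2.53 and decorin (Dcn) had -2.02 without passing (adjusted p = 0.0532), although it passed under several alternatives, among them median centring (0.0434) and 16 units added (0.00473), with a range over all alternatives from 4.421e-04 to 0.189. Of 8 tested endothelial markers, 1 fell, the VEGF receptor gene Flt1 at -2.05, and 1 rose, Emcn at 0.76 (1 rose and 2 fell adjusted over the list alone, median -0.25, camera adjusted p = 0.552). Of 12 tested microglia and macrophage markers, 2 fell, Cd68 at -1.17 and Fcer1g at -1.06, and 1 rose, Cd14 at 0.82 (the same counts adjusted over the list alone, median -0.13, and 0.04 with the authors' scaling, camera adjusted p = 0.963). The adjusted p rose to 0.0769 for Rgs5 without control array 2, 0.125 for Col1a2, 0.201 for Pdgfrb, 0.169 for Emcn, 0.0648 for Cd68 and 0.151 for Fcer1g without Eva1 shRNA array 1, and 0.088 for Cd14 without Eva1 shRNA array 2. The call of Pdgfrb (adjusted p = 0.0421) was also lost with median centring (0.0506) and with blank cells filled (0.0543). The fibroblast and pericyte members that rose numbered 1 whichever array was left out and those that fell 0, 1, 2 and 1 without control arrays 1 and 2 and Eva1 shRNA arrays 1 and 2, and 0 microglia members passed without control array 1 or Eva1 shRNA array 1. After adding 16 units the change was -0.86 for Rgs5, -0.39 for Fcer1g and 0.15 for Emcn, whose call was lost then, with blank cells filled and with eBayes trend.

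Of 10 tested housekeeping genes, 1 fell, 2 rose and 7 did not pass (2 fell and 2 rose adjusted over the list alone). The MHC light chain gene B2m fell by 1.25, and the transferrin receptor gene Tfrc (1.01) and the TATA-binding protein gene Tbp (0.73) rose. These 3 kept their signs under the authors' scaling (-1.02, 1.17 and 0.92). Actb and Hprt had changes of -0.03 each, which were 0.09 and 0.12 with the authors' scaling. The adjusted p reached 0.0615 for Tfrc and 0.174 for Tbp without Eva1 shRNA array 2, and Tbp was also lost with blank cells filled.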

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

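Of the settings compared here, only the count over every probe, named or not (2044 higher and 2084 lower), was chosen after the data were seen. Mpzl2 stayed past the threshold under every alternative, with log2 changes from -1.71 (16 intensity units added) to -3.29 and a highest adjusted p of 0.0234. The counts of 1720 higher and 1856 lower genes moved by over 1.5 times to 2714 higher genes with the authors' scaling, which shifted the median of all genes, and to 369 higher and 480 lower with treat against a 1.5-fold change, a stricter question. With 1 array left out they ranged from 544 to 1144 higher and from 735 to 1156 lower, where fewer samples remained. The 1659 genes at least 2-fold apart became 873 with 16 intensity units added, which shrinks the changes of dim genes. The 3 lists called became 0 with an estimated correlation, a test with little power on 2 residual degrees of freedom, and 10 with fry, which asks another question. With the replicate number as a block there were 1471 higher and 1631 lower genes and 2 lists called, the cholesterol synthesis list being lost (adjusted p = 0.0639). The calls of 6 named genes were also lost (Dhcr7, Insig1, Pfkfb3, Apaf1, Spred1 and Pdgfrb). Deviations of the arrays numbered 1 from their group means correlated at -0.01 across probes, and the arrays numbered 2 give the same value by construction. This single value gave no sign that the numbers pair the arrays. Of 137 named genes past the test, 86 kept their call whichever array was left out, 18 lost it under some other alternative, and 0 of 146 named genes changed sign. With an array left out, calls were lost more often among genes named after their values were seen than among those named by rule. Named genes were picked mostly for small p or large changes, so their shares do not stand for all genes called. Of all 3576 genes called, 2 changed sign with the mean of a gene's probes.

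The authors' scaling turned the medians of 7 lists that were not called, by raising every gene by 0.209 against median centring, under which 0 lists changed sign, so these turns are no change relative to other genes. The median was then 0.0029 for noncanonical NF-κB components, 0.16 for oligodendrocyte markers, 0.17 for neuronal markers, 0.0892 for CDK inhibitors and p53 targets, 0.0442 for apoptosis regulators, 0.12 for extracellular matrix genes and 0.0403 for microglia markers. Other turns were of lists not called, and their cause was not tested. Without the dimmest 25% of probes the median was 0.0812 for neuronal markers and -0.22 for Notch genes, and with blank cells filled it was -0.17 for fibroblast and pericyte markers. With 1 array left out it ranged from -0.16 to 0.12 for neuronal markers, -0.16 to 0.0378 for CDK inhibitors and p53 targets, -0.23 to 0.25 for Notch genes, -0.13 to 0.34 for BMP and TGF-β genes and -0.15 to 0.0730 for microglia markers. The number of arrays and the blank cells near background limit what can be said of dim genes.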

Other observations

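The symbol families and the tests of array scaling and of single arrays were chosen after the results were seen, while the tests of gene brightness, of the second hypoxia list and of the blank cells were written before their results were seen. Genes that share the stem of their symbol were tested as families, 226 families with at least 8 tested members each. Of these, 4 families stood above other genes with camera at its preset correlation, while 0 were called with an estimated correlation (adjusted p = 0.963 for each of the 4). The latter test rests on 2 residual degrees of freedom and had little power over 226 families. The Fzd family of Wnt receptors had 5 of 8 members higher and a median log2 change of 0.95, led by Fzd2 at 1.64, or 1.06 with 16 intensity units added (camera adjusted p of the family = 0.0388). Of 9 Exosc genes, which encode subunits of the RNA exosome, 5 rose, with a median of 0.83 and Exosc7 at 1.03 (camera adjusted p of the family = 0.0388). Of 28 Mrps genes, which encode proteins of the small mitochondrial ribosomal subunit, 10 rose, with a median of 0.27 and Mrps6 at 1.23 (camera adjusted p of the family = 0.0371). Of 9 Mcm genes, most of which encode the replicative helicase and overlap the cell cycle list, 7 rose, with a median of 0.78 and Mcm10 at 1.14 (camera adjusted p of the family = 0.0239). The adjusted p of the single gene Exosc7 in limma's test reached 0.0538 without Eva1 shRNA array 1.

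The cell cycle list stood above other genes at camera's preset correlation but was not called with an estimated one (adjusted p = 0.418), a test with little power here. Array scaling, gene brightness and a single array were looked at as technical explanations. The list's median was at least 0.79 under all 3 scalings. The authors' scaling and median centring differ by the same 0.209 for every gene, so the choice between them could not bring a median of this size near 0. Array scaling was therefore hardly put to a test. Against the brightness of the list's genes, the list's median lay at percentile 100 of 10000 lists matched on mean level, whose medians ran from -0.43 to 0.44. Against a single array, the median was at least 0.88 whichever array was left out. The hairpin, and any difference in how the cells of each group were selected or grown, stay open as explanations that were not tested.

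Most members of the hypoxia and glycolysis list were lower, with an open question of how dense or oxygenated the cultures were. The list's median was -0.72 or lower under all 3 scalings. The authors' scaling and median centring differ by the same 0.209 for every gene, so the choice between them could not bring a median of this size near 0. Against a single array, the list's median was -0.86 or lower whichever array was left out. Against the brightness of the list's genes, it lay at percentile 0 of the matched lists, whose medians ran from -0.57 to 0.56. Against a change confined to the genes of the fixed list, a second list of 26 tested hypoxia-inducible genes had a median of -0.56, with 13 lower, among them Higd1a (-1.27) and Bnip3l (-1.11), 0 higher and 13 not past the test (camera p = 4.429e-05, and p = 0.0448 with an estimated correlation, where the fixed list had p = 0.0727 and adjusted p = 0.672). A biological difference between the groups and a difference in culture conditions may each give this pattern, and no value here bears on that choice.

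With the authors' scaling 67.7% of the calls were higher in the Eva1 shRNA cells, against 48.1% after quantile normalization. The control arrays had more blank cells than the Eva1 shRNA arrays, and the authors' median was near 25 over the filled cells of each array. Blank cells thus stood outside the authors' median, which would raise it on the control arrays, where more dim probes were blank. That this gave the balance of calls is a candidate explanation. When each array was scaled to its median over all probes, with blanks ranked lowest, the median change of all genes went from 0.18 to -0.0362. Lining up the arrays at that median brings the median change near 0 almost by construction. The value therefore does not tell why the control arrays had more blank cells. A true rise of many dim genes in the Eva1 shRNA cells may also fill cells and was not tested.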
